A study of Oryza sativa Indica Group with 3 samples.

How the data were processed

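Rice grains of the cultivar TN1 were profiled by tag sequencing, in which each messenger RNA is represented by a short sequence next to a cut site of a restriction enzyme. Per the labels, the grains were taken 20 days after anthesis from pot-grown plants, total RNA was extracted with TRIzol and treated with DNase, and libraries followed Illumina's standard procedure. There were 3 groups with 1 library each, named here as the labels name them: control (no arsenic or sulfur added), 20As (20 mg arsenic per kg of soil) and 20As+120S (the same arsenic with 120 mg sulfur per kg). The labels give 4 pots per treatment and do not say whether a library came from 1 plant or from several, so no spread between plants could be measured.

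Each deposited file lists tags of 21 bases, with their copy numbers and a second value per tag. Per the file headers the copy number is a count of each tag, and the deposited counts are whole numbers that start at 2 in each library. Tags with 1 copy are thus not listed, and an unlisted tag was treated as having 0 or 1 copies. Every tag starts with CATG, the site cut by the enzyme NlaIII, followed by 17 bases, and no tag holds a letter other than A, C, G or T. The second deposited column is headed TPM by the authors. It was recomputed from the counts as copies relative to the listed total of the same library, and the largest difference was below 0.005, which is rounding. The software that made the tag lists, its filters and the reference the authors used are not given in the sources used here.

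The files pair no tag with a gene, and no transcript sequences were used here, so results are given per tag sequence, without gene names or genome positions. One gene can give several tags, and related genes can share 1 tag. The gene lists fixed before the data were examined (storage proteins, starch synthesis, sulfate assimilation, glutathione, arsenic transport and others) are defined by gene name and were not applied, and neither were the tissue markers. For the same reason the rule for named tags was used without its condition on a protein name: in each comparison the 10 tags with the largest positive and the 10 with the largest negative log2 ratio, and the 10 tags with the highest mean over the 3 libraries.

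From the counts, scaling factors were computed with edgeR 4.0.16 (trimmed mean of M values, TMM) in R 4.3.3, on the 13949 tags with a mean of at least 20 copies over the 3 libraries. The factors were 1.20 for control, 0.937 for 20As and 0.892 for 20As+120S. Log2 ratios were taken between scaled CPM (copies relative to the scaled library total) with a prior of 1 count. With 1 library per group no test across tags is possible, and no p-value is given for any comparison between groups. A size rule was used instead: at least 2-fold apart. Fold differences of single tags carry the exact conditional binomial 95% interval, and shares the exact Clopper-Pearson 95% interval. Both cover counting error only and treat copies as independent. Copies made by PCR are not independent molecules, so the intervals are too narrow to that extent. Where a tag was unlisted in either library compared, the fold is given as "at least" a value computed against 4.74 copies. That is the one-sided 95% upper limit when at most 1 copy was seen. Counting error of the listed copies is not included, so the value is not a strict lower limit.

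The listed totals were 3409255 copies for control, 3397919 for 20As and 3410974 for 20As+120S, which differ by at most 0.333% from control; tags seen once are not listed, so the sequenced totals are unknown. The size rule was tested on simulated data, drawn as independent copies from the tag means and library totals. Counting error alone put on average 29.4 tags at least 2-fold higher and 43.4 lower in 20As against control, 59.4 and 59.1 in 20As+120S against 20As, and 30.8 and 53.4 in 20As+120S against control, over 20 simulations each. Of 50 tags per size changed by a known amount in the simulation of 20As against control, the rule found 14.0% of those changed 1.5-fold, 96.0% of those changed 3-fold and 100.0% of those changed 4-fold.

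Alternatives fixed before the data were examined were scaling by total copies, DESeq2 1.42.0 size factors, no filter and a filter at a mean of 100 copies, a prior of 5 or 0.1, the deposited TPM values, and a 4-fold threshold. Alternatives added after seeing the data were TMM factors from all listed tags, totals without the 100 most abundant tags, ratios centred on the last 2 bases or on the GC count of the tag, merging of likely sequencing errors, merging of tags on their first 18 bases, and leaving out tags that end in 6 or more A or match the adapter. The comparisons used edgeR for scaling factors only. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.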

Results

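Developing rice grains from 3 soil treatments were compared to ask how arsenic in the soil, and sulfur given with it, relate to transcript levels in a cultivar that the labels describe as storing much arsenic in its grain. Each treatment was represented by 1 tag library, so no value below has a replicate error. The totals were 3409255 copies in control (no arsenic or sulfur added), 3397919 in 20As (20 mg arsenic per kg of soil) and 3410974 in 20As+120S (the same arsenic with 120 mg sulfur per kg). Together the libraries listed 141715 distinct tags, of which 54334 were found in all 3, 28874 in 2 and 58507 in 1. The 13949 tags that entered the comparisons carried 84.7% of the copies in the control library, 88.5% in 20As and 90.0% in 20As+120S.

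The grain transcriptome was dominated by a small number of tags, more so in both arsenic libraries than in the control. The 10 most abundant tags of each library held 23.7% of all copies in control, 30.3% in 20As and 34.2% in 20As+120S. The 100 most abundant held 43.5% (95% interval 43.4 to 43.5), 54.2% (54.1 to 54.2) and 57.7% (57.7 to 57.8). The number of distinct tags ran the other way, at 105702 in control, 90670 in 20As and 82885 in 20As+120S, at nearly equal totals of listed copies. The effective number of tags, the exponential of the Shannon entropy of the copies, was 3034 in control, 1400 in 20As and 1030 in 20As+120S.

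**Figure D1:**
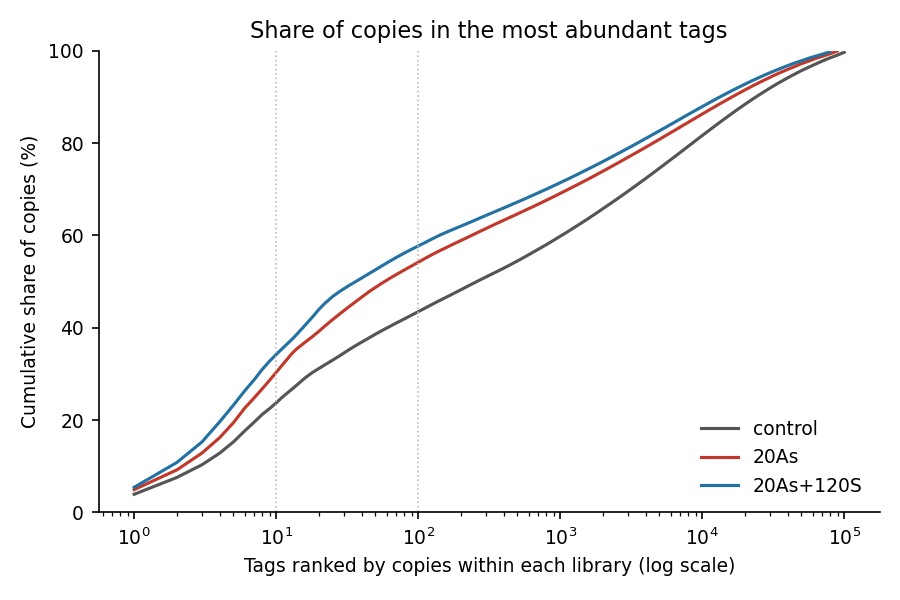
Cumulative share of copies (percent) against the rank of each tag within its library (log scale), 1 line per library; dotted lines mark ranks 10 and 100. The control line lies lowest at both marks, with 23.7% and 43.5% of the copies, and the 20As+120S line highest, with 34.2% and 57.7%.

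The first comparison, 20As against control, asked what differed when arsenic was added. With TMM scaling all 10 of the most abundant tags were higher in 20As, 2 of them at least 2-fold; scaled to total copies 8 were higher, none of them 2-fold, and CATGTACTCTAGTAATAAGGT and CATGTGAAACTTAAGGTGATA were lower. CATGTAATAAAATTTGGAATA stood at 9979 CPM, copies relative to the scaled library total, in control and 23810 in 20As, 2.39-fold higher (95% counting interval 2.36 to 2.42). CATGTGTGACTGTTGAAACTT stood at 15970 and 33610, with an interval of 2.084 to 2.125 on the fold. The smallest difference of the 10 was that of CATGTACTCTAGTAATAAGGT, at 1.05-fold (1.04 to 1.07). The 29 tags with a mean of at least 10000 copies had a median log2 ratio of 0.82, with 28 of them higher in 20As, and of 0.47 with 23 higher when scaled to total copies. The 189 tags with a mean from 1000 to 10000 copies had a median of 0.42 (0.06 with total copies), and the 8133 tags with a mean from 20 to 50 copies a median of -0.03.

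Across the 13949 tags, 919 were at least 2-fold higher and 1054 at least 2-fold lower in 20As than in control. For 230 of the higher and 208 of the lower tags the whole counting interval lay beyond 2-fold. Counting error alone gave at most 35 higher and 56 lower tags in 20 simulations. Scaled to total copies, the split was 355 higher and 2181 lower, since that scaling shifts the median log2 ratio of all tags to -0.35. The calls were spread unevenly over tag sequences: tags that end in GT made up 4.32% of the tags compared, 18.1% of the lower ones and 0.435% of the higher ones, and their median log2 ratio was -0.66.

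The largest differences were of tags found in 1 of the libraries and unlisted in the other. CATGTATGATGAATAAATGAT had 3064 copies in 20As and was unlisted in control, at least 828-fold higher. CATGAAACGCGTGGCGGCGAG followed with 2353 copies, at least 636-fold higher, CATGGCTCTCTCCGATAGGAG with 1379, at least 373-fold, and CATGCTTTCCCACCAACCCCA with 881, at least 238-fold. None of these was listed in 20As+120S either. No genome or transcript sequence was compared with the tags, so whether those listed in 20As alone come from rice is not known. Also unlisted in control were CATGGTCAGTAGCTAGGGTAT with 140 copies in 20As, CATGTACTATCAAAAAGAGAA with 126, CATGGAGGACGACGAACTGTC with 111 and CATGCAAGACTGCAGGCAGTG with 86. CATGCTGTCAGGCATCTACAG had 5 copies in control and 433 in 20As, 111-fold higher (47.2 to 344). CATGTCGGACTGTAGAACTCT, with 27 copies in control, 4772 in 20As and 1142 in 20As+120S, was taken to be CATG followed by the reverse complement of the end of the Illumina adapter for NlaIII tags. This identity rests on general knowledge of that adapter, which the labels do not give; if it holds, the copies do not measure a transcript.

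All 10 of the lowest tags were unlisted in 20As. CATGTGCACTAAAGATTGTGG had 199 copies in control, which makes it at least 32.7-fold lower in 20As. CATGGCAATTATCAATCTATT had 152, at least 25.0-fold lower, CATGAAGATGATGGCTTTGTC 128 and CATGCATACATAATTTGGGTT 122. The control library held 116 copies of CATGTATACTACGGTGGACCG, 94 of CATGTTTTAAGATCCAGGAGC and 92 of CATGGATTGCATCGTCGATCT. It held 91 copies each of CATGGCAATTATCAATCAAAA and CATGGCAATTATCAATCTAAA, which share their first 17 bases with the second tag of this group, and 89 of CATGGTGCTGGAGCTCGACGT. All 10 were unlisted in 20As+120S as well.

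**Figure D2:**
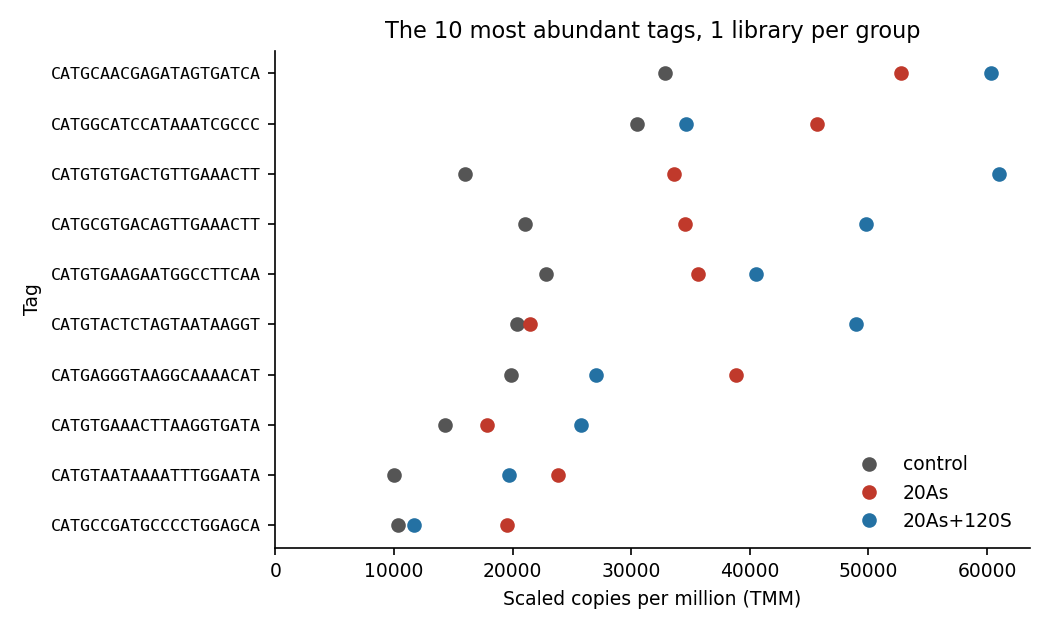
Scaled CPM (TMM) of the 10 tags with the highest mean over the 3 libraries, 1 point per library and no error bars because each group has 1 library. With this scaling the control point is the lowest of the 3 for every tag, whereas with total copies 4 of the 10 tags are lower than control in 1 of the arsenic libraries; CATGTGTGACTGTTGAAACTT stands at 15970, 33610 and 61040.

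The second comparison, 20As+120S against 20As, asked what differed when sulfur was given with the arsenic. Of the 10 most abundant tags, 6 were higher with sulfur and 4 lower, and 1 was at least 2-fold apart. CATGTACTCTAGTAATAAGGT stood at 21460 CPM in 20As and 48970 with sulfur, 2.28-fold higher (2.26 to 2.30). It ends in GT, and its log2 ratio of 1.19 was 0.42 after centring on the last 2 bases. CATGTGTGACTGTTGAAACTT stood at 33610 and 61040, 1.82-fold higher (1.80 to 1.83). CATGCCGATGCCCCTGGAGCA was lower by 1.67-fold (1.65 to 1.70), from 19500 to 11650, and CATGAGGGTAAGGCAAAACAT by 1.44-fold (1.42 to 1.45), from 38840 to 27020. The 29 tags with a mean of at least 10000 copies had a median log2 ratio of 0.29, with 18 of them higher.

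Across all tags compared, 883 were at least 2-fold higher and 809 at least 2-fold lower with sulfur, 146 and 91 of them with the whole counting interval beyond 2-fold. Counting error alone gave at most 77 higher and 71 lower tags. Scaled to total copies the split was 725 and 1018. Tags ending in GT made up 25.6% of the higher tags and 0.494% of the lower ones, with a median log2 ratio of 0.78. Those ending in TG made up 21.7% of the higher tags and GG 10.3%, while GC made up 13.7% of the lower ones and AG 12.4%.

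Of the 10 tags with the largest positive ratio, 9 ended in GT or TG, and 20As held 2 to 11 copies of each. CATGTGTGTTCAATGGAATTG had 2 copies in 20As and 36 with sulfur, 18.8-fold higher with an interval of 4.85 to 162. CATGTATAAAAATATGCTTGT had 4 and 40 copies, 10.5-fold higher (3.78 to 40.3), and CATGTGAGAGCATTTCTTTGT 5 and 49, 10.3-fold higher (4.11 to 33.0). CATGGTATCTAAACACTGTTG had 5 and 44 copies, and CATGGAGAAGGGCGACGAAAC, the one tag with another ending, 3 and 26. CATGTAACACTACATACCCGT had 11 and 79 copies, 7.51-fold higher (3.98 to 15.7). The others were CATGAAAGATCAAATGTCTGT with 3 and 25, CATGTCTTGTCACACTTTTGT with 4 and 30, CATGATGAGATTGAGATTCGT with 7 and 43, and CATGCTAGTTTCTTGAGAATG with 6 and 37. In control these 10 tags had 24 to 58 copies. Of the 10 tags with the largest negative ratio, 9 were among those named as highest in 20As against control, and all 10 were unlisted with sulfur. The tenth, CATGGTAATCCTCACTCGTAC, had 71 copies in 20As and was unlisted in control too.

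**Figure D3:**
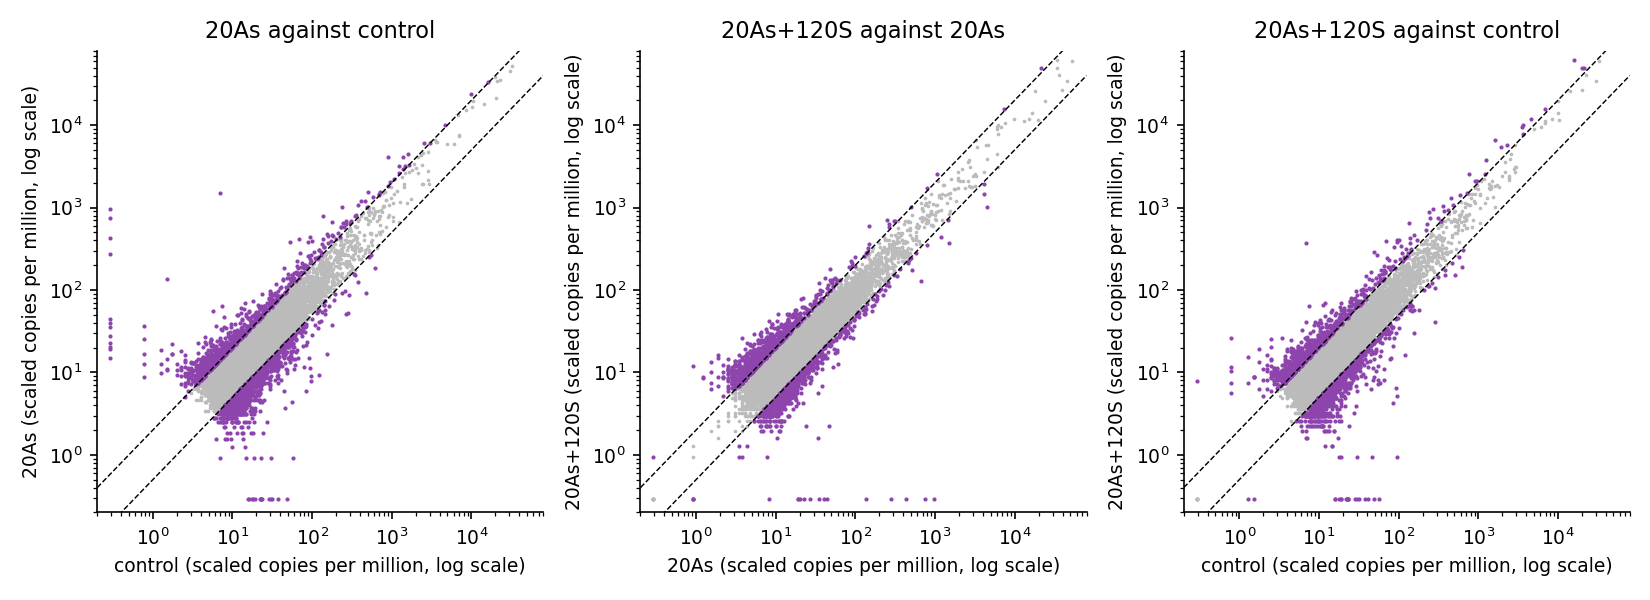
Scaled CPM (both axes on a log scale) of the 13949 tags compared, 1 panel per comparison; purple points lie at least 2-fold apart, beyond the dashed lines. The rows of points at the lower and left edges are tags unlisted in 1 library, and purple points number 1973, 1692 and 1687 from left to right.

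The third comparison set 20As+120S against control. With TMM scaling the 10 most abundant tags were all higher in 20As+120S, 3 of them at least 2-fold; scaled to total copies 8 were higher, 1 of them at least 2-fold, and CATGGCATCCATAAATCGCCC and CATGCCGATGCCCCTGGAGCA were lower. CATGTGTGACTGTTGAAACTT was 3.82-fold higher (3.79 to 3.86), CATGTACTCTAGTAATAAGGT 2.41-fold (2.39 to 2.43) and CATGCGTGACAGTTGAAACTT 2.36-fold (2.34 to 2.38). All 29 tags with a mean of at least 10000 copies were higher with TMM scaling, with a median log2 ratio of 0.87, and 25 of them, with a median of 0.45, when scaled to total copies. Of all tags compared, 805 tags were at least 2-fold higher and 882 lower, 189 and 156 of them with the whole counting interval beyond 2-fold, against at most 41 and 68 from counting error alone. Scaled to total copies the split was 271 and 2468, with the median of all tags at -0.42. Tags ending in AA made up 13.8% of the tags compared and 43.6% of the higher ones.

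The tag with the largest positive ratio was again the presumed adapter sequence, and CATGTCTGACTGTAGAACTCT, 1 base away from it, was also among the 10. CATGCAGTATTGCAGGCTTGC had 2 copies in control and 79 in 20As+120S, 53.0-fold higher (14.2 to 445), and 115 in 20As. CATGCTGGAGTGAGTGGATTG was unlisted in control and had 23 copies, at least 6.50-fold higher. CATGTCAGTTTTTGTGGCATG had 2 and 35 copies, CATGCTGGCGCGGCTGAAGCG 2 and 31, and CATGCTGTGTAATAAAGCAGA 4 and 46. CATGTACTCTAGTAATAAGCT had 6 and 58 copies, CATGTAGCTGAAGTAGCAGGC 9 and 76, and CATGGCCGAGGGGTTCCCCGG 29 and 193, the last 8.93-fold higher (6.02 to 13.7). The tag with 6 and 58 copies differs by 1 base from one of the 10 most abundant tags. That abundant tag had 83057 copies in control and 148971 in 20As+120S. Whether the 6 and 58 copies are sequencing errors of it was not tested, so they may not measure a separate transcript. Of the 10 tags with the largest negative ratio, 7 were among those named as lowest in 20As. The other 3 were CATGGCAATTATCAAAAAAAA, with 231 copies in control, 2 in 20As and none listed with sulfur, CATGCACAATGTATAACTTCT with 165, 25 and none listed, and CATGGAGTTTCAGAGCAGCAA with 391, 24 and 2. The last was 146-fold lower in 20As+120S than in control (40.1 to 1208).

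Whether tags stood closer to control with sulfur than without it was asked over all 3 libraries. In 3668 tags the highest and lowest scaled values were at least 2-fold apart. The library that stood apart from the others was control in 36.3% of them, 20As in 36.7% and 20As+120S in 26.99%. Values exchanged at random between the libraries within each tag would give 33.3% each. Control and 20As were thus close, at 1332 and 1346 tags, and their order depended on the processing: control had the larger share with total copies (43.5%, 26.9% and 29.6%), with a mean of at least 100 copies and after centring on the last 2 bases. With TMM scaling, of the tags at least 2-fold higher in 20As than in control, 194 were at least 2-fold lower again with sulfur. Permuting the 3 values within each tag, 100 times, gave 193 on average (160 to 217). For tags lower in 20As and higher again with sulfur the count was 442, against 369 (329 to 416); 20As is the library in which tags ending in GT were low. Tags higher in both arsenic libraries than in control numbered 370, against 367 (324 to 412), and tags lower in both 271, against 193 (166 to 226). Scaled to total copies these 4 counts were 101, 537, 132 and 862. Permuted values then gave 330 (300 to 366), 423 (386 to 474), 421 (370 to 465) and 329 (284 to 361). The 2nd and 4th counts thus exceeded the permuted range with both scalings, the other 2 fell below it with total copies only. The permutation treated tags as independent and kept no difference that runs through a whole library. Its ranges thus do not measure chance between plants or library preparations. Total copies shift the median of all tags to -0.35 and -0.42 against control, so the balance between tags higher in both and lower in both depended on the scaling. Independent lists would share 53.0 higher and 66.6 lower tags, but both comparisons use the control library, which alone makes lists overlap, and with 1 control library it could not be split. The covariance of the 2 sets of log2 ratios against control was 0.316, and 0.273 on average in the permuted values (0.242 to 0.305); with total copies it was 0.318, against 0.324 (0.290 to 0.357).

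**Figure D4:**
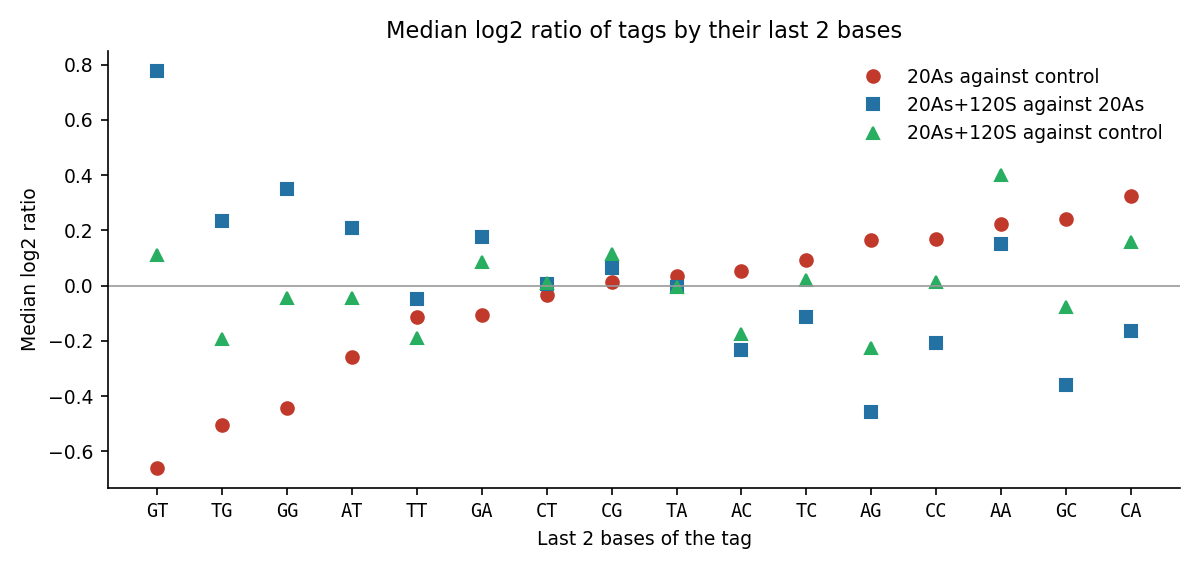
Median log2 ratio of the tags compared, grouped by their last 2 bases, for each of the 3 comparisons; points are medians over tags and the line marks 0. Tags ending in GT lie at -0.66 in 20As against control and at 0.78 in 20As+120S against 20As, but at 0.11 in 20As+120S against control.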

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

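Scaling by total copies left the number of tags at least 2-fold apart within 1.5 times of the reported count in 20As against control (2536) and in 20As+120S against 20As (1743), but raised it to 2739 in 20As+120S against control; the deposited TPM values gave 2700 there. Settings that change which tags enter, or the threshold, moved all 3 counts by construction: without a filter they were 71634, 62729 and 70984, with a mean of at least 100 copies 352, 214 and 270 (215 higher and 137 lower in 20As against control and 169 and 101 in 20As+120S against control, where fewer were higher than lower as reported), and at 4-fold 185, 94 and 158. The other alternatives kept the counts within 1.5 times, DESeq2 size factors sharing 1962 of the 1973 calls in 20As against control. The alternatives for TMM factors from all listed tags, totals without the 100 most abundant tags, centring, merging and leaving out A-ending tags were chosen after seeing the data. Centring on the last 2 bases kept 62.9%, 58.6% and 74.4% of the calls of the 3 comparisons. Total copies kept 71.41%, 90.66% and 68.35% of them, and centring on the GC count 91.13%, 78.55% and 78.84%. Similar counts thus do not mean the same tags. The library that stood apart was control in 43.5%, 20As in 26.9% and 20As+120S in 29.6% of tags with total scaling. With a mean of at least 100 copies the shares of control and 20As+120S were 44.3% and 18.2%, and after centring on the last 2 bases those of 20As and 20As+120S were 32.3% and 30.4%; the cause of these moves was not tested. For the tags with the largest ratios, 60 comparisons of tags, all 727 values under the alternatives kept their sign and stayed at least 2-fold apart, 39 of them outside the counting interval. These tags were selected for their large ratios, the smallest in size being a log2 ratio of 2.52. The outcome was thus nearly fixed by the selection and says little on other tags. For the 10 most abundant tags 382 of 390 values kept their sign, 10 values of tags reported as at least 2-fold apart were under 2-fold, and 2 values of tags reported as under 2-fold were at least 2-fold. The 8 opposite signs came with total copies and with the deposited TPM values, which gave equal log2 ratios: -0.28 for CATGTACTCTAGTAATAAGGT and -0.0318 for CATGTGAAACTTAAGGTGATA in 20As against control, and -0.24 for CATGGCATCCATAAATCGCCC and -0.25 for CATGCCGATGCCCCTGGAGCA in 20As+120S against control. The log2 ratio of CATGTACTCTAGTAATAAGGT in 20As+120S against 20As was 0.42 after centring on the last 2 bases, where 1.19 was reported. Scaling without storage protein genes, and the gene list alternatives, were not run because tags carry no gene names. No paired analysis was possible because each group has 1 library, which also rules out leaving a library out. A tag with few copies is limited by depth: the 2 copies of CATGTGTGTTCAATGGAATTG in 20As leave its fold anywhere between 4.85 and 162.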

Other observations

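The tests of this part were chosen after the result was seen, except those of GC content, of overlapping tags and of abundant tags centred on their last 2 bases. The tags named in this part outside the rule for named tags were chosen after their values were seen. Among tags with a mean of at least 1000 copies, 16 pairs differed by 1 base, 15 of them with the same last 2 bases, so that the balance within these 15 does not reflect the last 2 bases; an effect of the base that differs was not tested. Substitutions are given from the more abundant tag to the other, counted from 1 at the 5' end of the tag. CATGTGAAAAATGGCCTTCAA (G9A) made up 30.8% of the copies it shares with CATGTGAAGAATGGCCTTCAA in control, 31.7% in 20As and 25.7% in 20As+120S (95% interval 25.5 to 25.9). CATGTGAAACTTTGGGTGATA (T19A against CATGTGAAACTTTGGGTGTTA) made up 21.4%, 28.4% and 16.1%. CATGCAACAATAGCAAGGAGA (G7A against CATGCAGCAATAGCAAGGAGA) made up 47.0%, 38.9% and 34.2%. Of the 15 pairs, the intervals of 20As and control lay apart in 9 and those of 20As+120S and 20As in 8, so the differences in balance exceeded counting error there; spread between plants is unknown.

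Tags that run into A, as when a messenger RNA ends within the tag, were more frequent in both arsenic libraries. Tags ending in 6 or more A held 3.58% of the copies in control, 4.96% in 20As and 6.29% in 20As+120S (95% interval 6.27 to 6.32). Of the 482 such tags compared, 210 were at least 2-fold higher and 3 lower in 20As+120S than in control, with a median log2 ratio of 0.93, and 147 and 3 in 20As against control, with a median of 0.66. The 896 tags ending in exactly 2 A had medians of 0.10 in both. In 12 pairs of an A-ending tag and a tag with the same start that reads on, the A-ending share was lowest in control in 10, and that of 20As was above control with intervals apart in 8. The share was highest in 20As in 8, and 20As+120S lay below 20As with intervals apart in 6, unlike the order of the total shares. In 6 of the 12 pairs the members differed in their last 2 bases; in the other 6 the share was lowest in control in 5 and highest in 20As in 4. Of these, CATGTTGTTGCAAAAAAAAAA made up 7.30% of its pair with CATGTTGTTGCAGCTATGTAA in control, 11.2% in 20As and 10.1% in 20As+120S, and CATGTTGTTGCAGCTAAAAAA made up 13.1%, 15.4% and 17.9% of its pair with the same tag.

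The presumed adapter sequence, identified from general knowledge and not from the labels, and tags within 2 bases of it held 44 copies in control, 5075 in 20As and 1246 in 20As+120S, or 0.00129%, 0.149% and 0.0365% of the copies, and the sequence itself had rank 5 among the tags by ratio of 20As to control.

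The log2 ratios followed the last 2 bases of the tag, which explained 11.6% of their variance in 20As against control, 13.7% in 20As+120S against 20As and 6.62% in 20As+120S against control, where the highest value of a neighbouring pair that shares no base with them was 2.46%, 4.17% and 4.60%. Miscalled bases among the listed tags were argued against, since adding together tags with the same first 18 bases left 11.9% and 14.1% in the comparisons with 20As. Variants seen once are not listed and could not be added back, so miscalls of tags with few copies were covered only in part. GC count alone explained 2.16%, 7.47% and 5.83%, and among tags with equal GC counts the last 2 bases still explained 11.1%, 13.9% and 5.22%, so GC content was argued against as the whole cause in the first 2 comparisons, and in the third explained nearly as much as the last 2 bases. A change in the transcripts themselves was argued against: in 96 pairs of overlapping tags, 1 tag holding a second CATG at which the other starts, the difference in ratio followed the difference expected from the last 2 bases with a slope of 1.03 (bootstrap 95% interval 0.774 to 1.30), where tags of 1 transcript should not differ. The dependence was not confined to that end, since the first base after CATG, position 5, explained 3.09% in 20As+120S against 20As and 3.39% in 20As+120S against control, where position 21 explained 3.89% and 4.16%; the step that gave rise to it was not tested.

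The lower number of distinct tags in both arsenic libraries was not explained by depth: the largest deficit in listed copies was 0.333%, whereas the control library thinned at random to as few tags would list 23.5% fewer copies for 20As and 34.3% fewer for 20As+120S. Copies of tags seen once are not listed, so the sequenced totals are unknown. For the higher TMM-scaled ratios of abundant tags against control, bias by the tag end was argued against as the whole cause. After centring, the 29 most abundant kept median log2 ratios of 0.58 (bootstrap 95% interval 0.42 to 0.72) of 0.82 in 20As. In 20As+120S they kept 0.80 (0.57 to 1.10) of 0.87. Scaled to total copies, the scale of the shares, the medians were 0.47 and 0.45 before centring, and centring was not run there. How much of the higher share comes from the tag end is thus not settled. Distinct tags were 14.2% fewer in 20As and 21.6% fewer in 20As+120S than in control. Without the 100 most abundant tags and at equal totals the deficits were 3.01% and 6.98%. Displacement by these 100 tags thus left a deficit in both libraries, the smaller in 20As. Displacement by the tags ranked next was not tested, so displacement as a whole stays open. With 1 library per group, arsenic cannot be told apart from plant or library preparation.

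The 11 tags with at least 60 copies in 20As and unlisted in both other libraries, 8335 copies in all, stood against 14 such tags in control, with 1449 copies, and 0 in 20As+120S. All 11 lacked a neighbour 1 substitution away with at least 50 times their copies, but this does not decide on sequencing errors. No tag in 20As exceeded 167986 copies, so for those of the 11 with the most copies few tags could qualify. Errors that insert or delete bases were not covered. A close neighbour listed in all 3 libraries (1 substitution, or 1 to 2 bases inserted or deleted) was found for 5 of the 11, 45.5%. It was found for 20.5% of 220 matched tags (two-sided Fisher's exact p = 0.0633), and for 0 of the 14 tags in control. Sequence variants carried by the sampled plants thus remain a hypothesis that this test does not decide, and an origin outside rice was not tested. CATGTGTGGAAGTTGAATCTC (G16A) had 64 copies in 20As, where its neighbour CATGTGTGGAAGTTGGATCTC had 10, against 36 in control and 25 in 20As+120S. The neighbours of the other 4 stayed abundant in 20As: that of CATGCTTTCCCACCAACCCCA (C21A, 881 copies) had 212 copies there, 291 in control and 249 in 20As+120S, and the remaining 3 had 269, 10439 and 438 in 20As, against 304, 9926 and 556 in control and 215, 7392 and 528 in 20As+120S.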
